A study of Mus musculus with 4 samples.

How the data were processed

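RNA of hippocampal microvessels, collected by laser capture from male mice, was measured on 4 arrays, 1 for each pairing of genotype (wild type or Ldlr knockout) and diet (control or western). Per the labels' protocols, total RNA was isolated with a PicoPure kit, 125 pg was amplified with the GeneChip WT Pico kit and the product was labelled with biotin. Per the series design text, the RNA of 3 mice was pooled for each group. The pooling leaves no spread between mice in the values, and 1 array per group leaves no replicate, so no test, p-value or standard deviation between replicates was computed.

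The deposited table holds 1 value for each of 34472 probe sets on each array, and the range and shape of the values show log2 signals. Transcriptome Analysis Console 3.1.0.5 is named in the submitters' processing notes. The background correction, the summarization of probes and the normalization between arrays are not given in the sources used here. The distributions were not equal between arrays, with a 95th percentile of signal of 3.31 in wild type on control diet, 2.86 in wild type on western diet, 5.94 in knockout on control diet and 5.71 in knockout on western diet. The number of arrays limits the precision.

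Probe sets were named from GEO's platform annotation. Of them 23521 had 1 symbol, 1820 had several and 9131 had none, and 23328 of those with 1 symbol were matched by gene ID to a mouse gene table (GRCm38.p6), which changed 0 symbols. That table served for names, RNA classes and the order of genes. No gene was named from a probe set with several symbols. A gene with several probe sets was represented by the one with the highest mean over the 4 arrays, which left 22180 genes. No probe set was annotated to Ldlr, so the targeted gene could not check the labels.

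The comparisons, the expression limit, the threshold, 30 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The expression limit was the median over genes of the mean log2 signal (2.18), and 11100 genes at or above it were counted at a log2 difference of 1 or more in size. The 5 comparisons were western minus control diet in each genotype, knockout minus wild type on each diet, and knockout on western diet minus wild type on control diet. The difference between both diet differences was computed per gene. Genes past the threshold the same way in both diet differences, or in both genotype differences, were set beside n1 × n2 / N, which gives 9.20 higher and 121 lower for diet, and beside the same product within bins of mean level.

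The lists held cell type markers (endothelial, mural, astrocyte, neuron, oligodendrocyte, microglia, fibroblast, choroid plexus, red blood cell and blood leukocyte) and pathway genes, with chemosensory receptor genes for noise and male and X-inactivation genes for the labels. The median of each list over all measured members was placed among those of 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays. The brightest bin spans a wide range of signal, so the matching is loose for the brightest genes. The red blood cell list had 2 measured members and was given no median, so 27 lists were placed. Members past the threshold were counted among those at or above the expression limit.

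The genes named are the 10 highest and 10 lowest of each comparison, up to 4 members of each list by size of difference in each comparison, the 10 largest shared differences, the 10 largest differences between diet differences in each direction, and cell type markers, leaving out predicted genes and small RNAs. The wording Rn among the small RNAs was read as ribosomal, nuclear and Y RNAs, which admits Rnf125. Genes outside the rule are named as such where they appear. Rbmxl1, Zfp955b, Zfp53 and Gstm7 belong to families of close copies, and Rab26os, Cep83os and Epb41l4aos are antisense to other genes, so their probe sets could share signal.

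Several choices were made after the data were seen. The floor of each array is the 95th percentile of 1429 chemosensory receptor genes, which gave 1.90 and 1.88 in wild type and 2.66 and 2.78 in knockout, control diet first. A named gene whose dimmer array lay at or below its floor has its difference given as a bound. A list was called where its median lay outside the central 95% of random lists, and a stricter limit was used for the closer look at differences between diet differences. The criteria for a larger vessel share and for lower cDNA yield were made stricter after their values were seen, which left both explanations open. Chosen after as well were the expectation within bins of mean level, the alternatives of arrays centred on their medians and of genes above the floor, the lists without endothelial and mural markers, random lists matched on the mean of the arrays compared alone, the RNA classes, the Ldlr neighbour test relative to the median of all genes, and 6 further lists, some of whose members had first been noticed among the genes with the largest differences. An error in the look-up of older symbols, which had put 3 wrong genes into the oligodendrocyte, ribosomal protein and mitochondrially encoded lists, was corrected after results had been seen. The correction moved the oligodendrocyte median with diet in knockout from near the edge of the random range to well inside it; it was not called before or after.

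The alternatives fixed beforehand were quantile normalization, cyclic loess, the 75th percentile as expression limit, a 1.5-fold threshold, the mean of a gene's probe sets, and lists restricted to members above the limit. Centring the arrays adds a constant to every gene and cannot move a list among random lists, so list calls were compared over the other 4 alternatives. Quantile normalization and cyclic loess were run in R 4.3.3 with limma 3.58.1, and everything else in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

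The steps were tested on simulated data that took the whole observed spread of each diet comparison as noise, with 200 of 11100 genes changed. In the wild-type diet comparison 51.5% of genes changed 2-fold, 98.5% of those changed 4-fold and 100% of those changed 16-fold passed the threshold, and 670 genes passed it with no change put in. In the knockout diet comparison the shares were 49.5%, 85.5% and 99.0%, with 2990 genes past it with no change put in. A list of 24 genes shifted by 1 had a median of 1.04 in the wild-type simulation and 1.03 in the knockout one, both at percentile 100, and 6 of 100 lists with no shift lay outside the central 95% in each, over 22180 genes.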

Results

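Hippocampal microvessels were cut out by laser capture from male mice, and their RNA was measured on 4 gene expression arrays. The arrays held wild-type C57BL/6J mice and mice without the low-density lipoprotein receptor (Ldlr knockout), each fed a control chow or a western diet for 8 weeks from the age of 5 weeks. Each array carried RNA pooled from 3 mice, so every group had 1 array, no difference below has a replicate check, and no p-value is given. Values are log2 signals. A difference is the first array minus the second, and a gene was counted as higher or lower at a difference of at least 1, which is 2-fold. Where the dimmer array lay at or below its floor, described with the array signals, a named gene's difference is a bound, the brighter array minus that floor, and is given as at least that value, or as that value or lower, while counts and lists use the measured values.

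Signals of different probe sets are not comparable as amounts of RNA, so each list of cell type markers is compared with itself between arrays. Neuron markers had a median signal of 3.35 in wild type on control diet, 3.17 in wild type on western diet, 6.64 in knockout on control diet and 5.43 in knockout on western diet. Endothelial medians were 2.21, 2.24, 3.43 and 6.02 in the same order, and mural cell markers, which belong to pericytes and smooth muscle, had medians of 1.78, 1.99, 3.11 and 4.51 over the 4 arrays. Of the Y-linked genes of the list fixed for sex, Kdm5d lay above the floor on all 4 arrays, Eif2s3y in wild type on western diet and in knockout on control diet, and Uty in knockout on control diet alone. Xist, which inactivates the X chromosome in females, lay below it on all 4.

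The arrays differed in overall signal. The median of all probe sets was 1.66 and 1.65 on the wild-type arrays and 2.48 and 2.53 on the knockout arrays, control diet first. A floor was set on each array from 1429 chemosensory receptor genes, and 6478 and 6041 of 22180 genes lay above it in wild type against 10446 and 9556 in knockout. No probe set was named for Ldlr, so the targeted gene could not be read on these arrays.

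**Figure D1:**
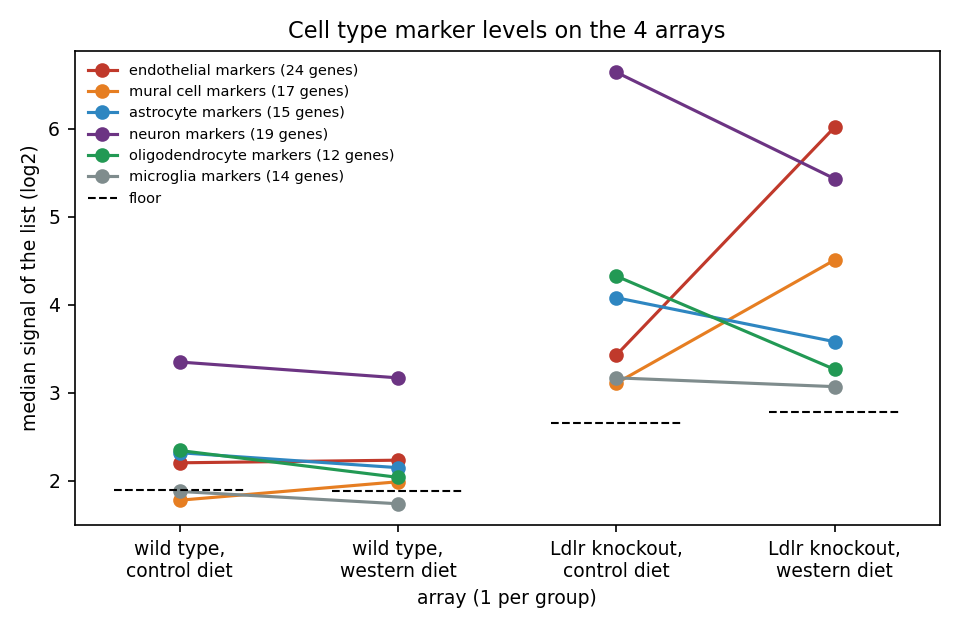
Median log2 signal of 6 cell type marker lists on each of the 4 arrays, with the floor of each array as a dashed line. The endothelial median is 3.43 in knockout on control diet and 6.02 in knockout on western diet, and all 6 lists lie lower on both wild-type arrays than on the knockout arrays.

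The comparison of western with control diet in knockout mice asks how the diet altered vessel transcripts where circulating lipoproteins are poorly cleared. Vessel genes were higher on western diet. Nid1, the basement membrane linker nidogen-1, had a signal of 8.33 on western diet and lay below the floor on control diet, a difference of at least 5.67. Pdgfrb, the growth factor receptor of pericytes, was higher by 5.20, Mgp, a matrix protein that inhibits calcification, by 4.88, and Abcb1a, the P-glycoprotein efflux pump of the blood-brain barrier, by 4.81. In all, 851 of 11100 genes were higher and 2037 lower.

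Of 23 endothelial markers above the expression limit, 18 were higher and 1 was lower. Eng, a co-receptor of transforming growth factor beta, was higher by at least 4.56, Pecam1, an endothelial adhesion molecule, by 4.25, Emcn by at least 2.94 and the tight junction protein Cldn5 by 3.01, while the angiopoietin receptor Tek was lower (-1.05). The median over all 24 measured members was 1.79, above all 10000 random lists of the same size and signal level (percentile 100). Of 12 mural cell markers, 8 were higher and 0 lower, among them Rgs5 (2.78), Vtn (2.36) and Myh11, the smooth muscle myosin (1.77), with a list median of 0.94 (percentile 100). Of 18 neuron markers, 0 were higher, 12 lay between the thresholds and 6 were lower, including Nrgn (-2.72), Calb1 (-2.11) and Grin2b (-1.77). The neuron median of -0.64 (percentile 8.67) and the oligodendrocyte median of -0.57 (percentile 12.4) lay inside the central 95% of random lists, and 5 of 12 oligodendrocyte markers were lower, with Mag at -1.98. With random lists matched on the mean of the arrays compared alone, a choice made after the data were seen, neuron markers lay just outside (percentile 2.49).

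Haemoglobin signal, a mark of blood, was higher on the same array: of 5 probe sets annotated to several haemoglobin genes, 3 were higher and 0 lower, at 9.12 against 7.48, at 8.19 against 5.71 and at 4.11 against a value below the floor. The medians of the other vascular lists lay above 0. Blood-brain barrier transport genes had a median of 0.46 (percentile 99.99), with 6 higher and 1 lower of 17, among them Slc22a8, an organic anion transporter (4.25), and Slc6a6, the taurine transporter (3.04). Basement membrane and matrix genes had a median of 0.51 (percentile 99.99), with 6 of 18 higher, including Lamb2 (2.47), Itgb1 (1.99) and Timp3 (1.83), and 1 lower. Angiogenic and vasoactive genes had a median of 0.34 (percentile 99.9), with the vascular endothelial growth factor receptors Flt1 (2.21) and Kdr (1.51) and with Notch4 (1.34) among 4 higher of 14, and 1, Tek, lower. Junction genes had a median of 0.29 (percentile 99.1), with 6 of 13 higher and 0 lower, led by Lsr, a protein of tricellular junctions (3.43), and Tjp1 (1.60). Some of these members are endothelial markers too. Without them, a comparison chosen after the data were seen, the median was 0.29 for 19 angiogenic genes (percentile 99.7), 0.21 for 19 transport genes (97.46) and 0.24 for 17 junction genes (97.2), the last pair inside the central 95%.

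Interferon-stimulated genes had a median of 0.26 (percentile 99.1, called in 3 of 4 alternatives), with Xaf1 (2.55), Iigp1 (1.55), Ifit3 (1.04) and Ifit1 (at least 0.67) higher of 13 and 0 lower. The endothelial markers were higher on the same array. Of 10 inflammation and endothelial activation genes above the limit, 5 were higher and 0 lower, among them Il6ra, the interleukin 6 receptor (3.22), the NF-kappa B subunit Rela (2.48), the chemokine Cxcl12 (1.78) and Nfkbia (1.42), and the list median was 0.12 (percentile 87.3). With members above the limit alone that list lay at percentile 100. The limit uses the mean of all 4 arrays, so members high only in knockout on western diet can pass it. Cholesterol synthesis genes had a median of -0.37 (percentile 6.56), with 6 of 17 lower, including Ebp (-2.09), Srebf2, the transcription factor that drives the pathway (-1.97), and Insig1 (-1.63), and 1 higher. That list lay below the central 95% under quantile normalization (percentile 1.34), under loess (1.08) and with members above the limit alone (2.25). Among immediate early genes 5 of 17 were lower, including Arc (-2.69) and Nr4a1 (-2.52), both induced by neuronal activity, and Btg2 (2.68) and Klf6 (2.25) were higher, with a median of -0.10 (percentile 43.1). Of the neuron markers, 6 were lower on the same array. A few members outside the rule for named genes were added after their values were seen: Slc3a2 (-1.67 or lower), Mmp2 (-1.08) and Fdps (1.19) were the exceptions in direction among transport, matrix and cholesterol synthesis genes, Nos3 (1.04) and Cxcl10 (at least 0.71) completed the angiogenic and inflammation counts, and Egr1 (-1.33) the immediate early count with Junb (-1.86) and Egr2 (-1.75).

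Among the genes lowest on western diet in knockout mice were Zfp955b, a zinc finger gene with close copies (-5.12 or lower), Fbxl16 (-4.99), Aph1a, a subunit of gamma-secretase (-4.82), and Exosc1, a subunit of the RNA exosome (-4.63). Aph1a and Bace1, the beta-secretase (-3.83), led an amyloid and tau list with 3 of 14 lower, 0 higher and a median of 0.08 (percentile 83.8). Faim2 (-4.56), Syt17 (-4.53) and the calcium channel subunit Cacna2d3 (-3.98 or lower) were among the 10 lowest. Rnf125, a ubiquitin ligase (5.48), Gstm7, of the closely related glutathione transferases (5.43), Fuz (5.20), Ndufa11 of respiratory complex I (5.19), Emp2 (at least 4.62) and Kank3 (4.97) completed the 10 highest.

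The remaining lists lay inside the central 95% of random lists in this comparison. Their medians were -0.30 for astrocyte markers (percentile 32.1), -0.05 for microglia markers (46.0), -0.11 for fibroblast markers (41.0), 0.22 for choroid plexus markers (93.7), 0.10 for blood leukocyte genes (66.3), -0.12 for LXR and cholesterol efflux genes (48.8) and -0.09 for fatty acid uptake and oxidation genes (14.0). They were -0.25 for antioxidant and oxidase genes (16.4), -0.08 for unfolded protein response genes (61.4), -0.32 for oxidative phosphorylation genes (18.2), -0.03 for ribosomal protein genes (64.0), -0.17 for apoptosis genes (7.68), -0.13 for insulin signalling genes (51.2) and 0.08 for cell cycle genes (71.7). Within them Xbp1, a transcription factor of the unfolded protein response (-3.31), Acadm and Acadl, which oxidise fatty acids (-2.50 and -1.97), and the glutamate transporter Slc1a3 of astrocytes (-2.20) were lower. Igf1r, the insulin-like growth factor receptor (1.69), was higher. In this comparison 513 of the genes past 2-fold, 17.8%, were at or below the floor on an array, as were 2 of the 10 highest and 4 of the 10 lowest genes on the dimmer array. Quantile normalization gave 744 genes higher and 935 lower and loess 1197 and 1510, so the size of the excess of lower genes depended on the scaling.

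**Figure D2:**
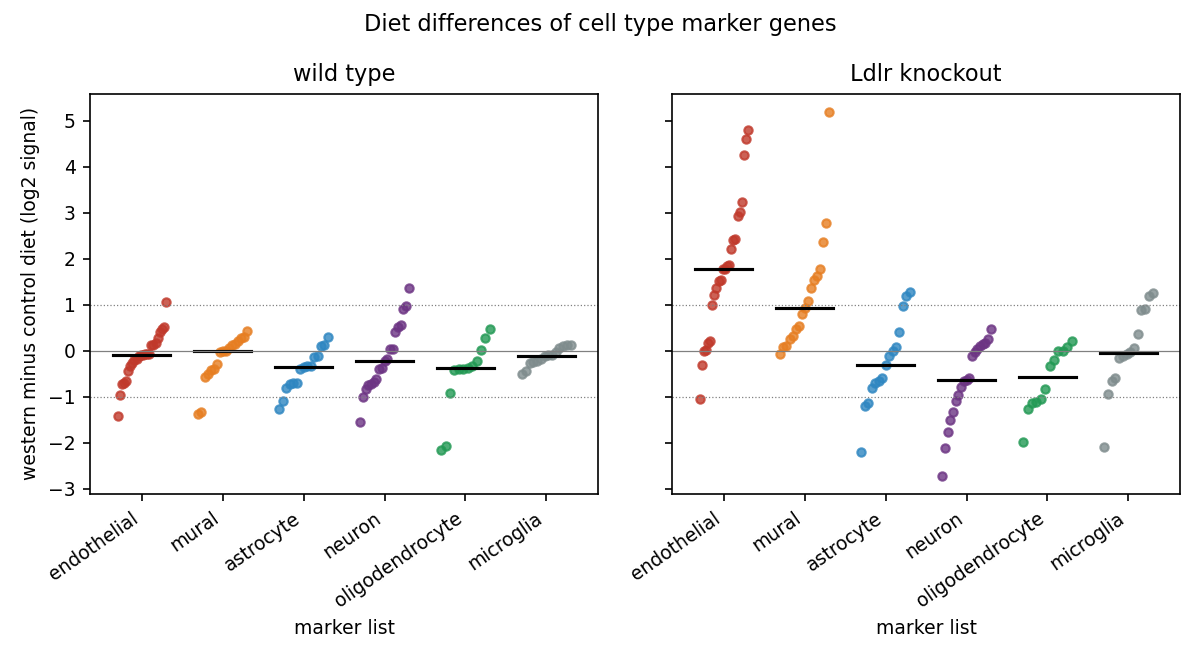
Difference of western minus control diet in log2 signal for each measured member of 6 cell type lists, in wild type on the left and Ldlr knockout on the right, with 1 point per gene, the list median as a bar and dotted lines at 1 and -1. The endothelial median is 1.79 in knockout and -0.10 in wild type.

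In wild-type mice the same comparison asks what the diet did with the receptor intact. Of 11100 genes, 120 were higher and 658 lower on western diet, but this split depended on the scaling: quantile normalization gave 821 higher and 746 lower, and loess 260 and 374. Vdac3, a channel of the outer mitochondrial membrane, was among the lowest (6.57 on control diet, 2.53 on western diet, difference -4.04), with Ppp1r7, a regulatory subunit of protein phosphatase 1 (-3.72 or lower), the antisense transcript Rab26os (-3.52) and Rbmxl1, a copy of an RNA-binding protein gene (-3.24 or lower). Among the highest were Purg (at least 2.85), the small GTPase Rap1b (at least 2.68), the neuropeptide Npy (2.49), Uqcrb of respiratory complex III (2.46) and Bsg, a partner of lactate transporters (2.14).

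Hadh, an enzyme of fatty acid oxidation (-2.76 or lower), Atp1b3, a subunit of the sodium pump (-3.10 or lower), and the GTPase Cdc42 (-3.04) were also among the 10 lowest, and Eif4h (2.23), S100a11 (at least 1.95), Ptgds, which makes prostaglandin D2 (1.93), and the transcription factor Nfib (1.91) among the 10 highest. Of 37 oxidative phosphorylation genes above the limit, 12 were lower and 1 higher, with Ndufs4 (-2.48), Cyc1 (-1.93) and Ndufa4 (-1.92) the lowest. Their median of -0.15 nevertheless lay inside the range of matched lists (percentile 80.4), as random lists of that brightness had a median of -0.24. The brightest 2218 genes by mean signal had a median of -0.33.

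Oligodendrocyte markers had a median of -0.38 (percentile 1.0), with Opalin (-1.89 or lower) and Mag, a myelin glycoprotein (-2.08), lower of 12 and 0 higher. That call held in 3 of 4 alternatives and was lost under quantile normalization (percentile 5.93) and with lists matched on the arrays compared alone (2.62). Interferon-stimulated genes had a median of 0.10 (percentile 98.2), with 0 of 13 past 2-fold, and were called in 1 of 4 alternatives. Endothelial markers had a median of -0.10 (percentile 70.0), with Ptprb higher (1.07) and the glucose transporter Slc2a1 lower (-1.42) of 23. Mural cell markers had a median of -0.01 (percentile 83.6), with Rgs5 (-1.38) and Myl9 (-1.34) lower of 12. Slc7a5, the large neutral amino acid transporter, was lower by the most among transport genes (-2.28). Tjp1 (-1.19), Hsp90b1, a chaperone of the endoplasmic reticulum (-2.21), Ncstn, of gamma-secretase (-1.45), and Klf6 (-1.99) were lower too, and Fabp5, a fatty acid binding protein, was higher (1.33).

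The other lists lay inside the central 95% in wild type on the deposited values. Their medians were -0.35 for astrocyte markers (percentile 3.61, but 0.515 under quantile normalization and 1.95 under loess, outside the central 95%), -0.23 for neuron markers (52.1), -0.11 for microglia markers (25.6), 0.01 for fibroblast markers (76.1), -0.06 for choroid plexus markers (25.2), 0.00 for blood leukocyte genes (58.6), 0.02 for junction genes (84.3) and -0.11 for transport genes (32.9). They were -0.02 for cholesterol synthesis genes (67.3), 0.03 for LXR and cholesterol efflux genes (83.8), -0.02 for fatty acid genes (59.4), -0.02 for inflammation genes (52.9), 0.00 for antioxidant genes (81.7), -0.17 for unfolded protein response genes (29.7) and -0.03 for ribosomal protein genes (92.5). They were -0.13 for basement membrane genes (14.0), -0.10 for angiogenic genes (24.7), -0.10 for apoptosis genes (17.4), -0.10 for insulin signalling genes (44.2), -0.35 for amyloid and tau genes (8.60), 0.04 for immediate early genes (89.6) and -0.01 for cell cycle genes (59.0). Where genes past 2-fold had other probe sets above the floor, 70 of those 115 probe sets differed in the same direction, which is 60.9%. The dimmer array was at or below the floor for 4 of the 10 highest and 4 of the 10 lowest genes.

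**Figure D3:**
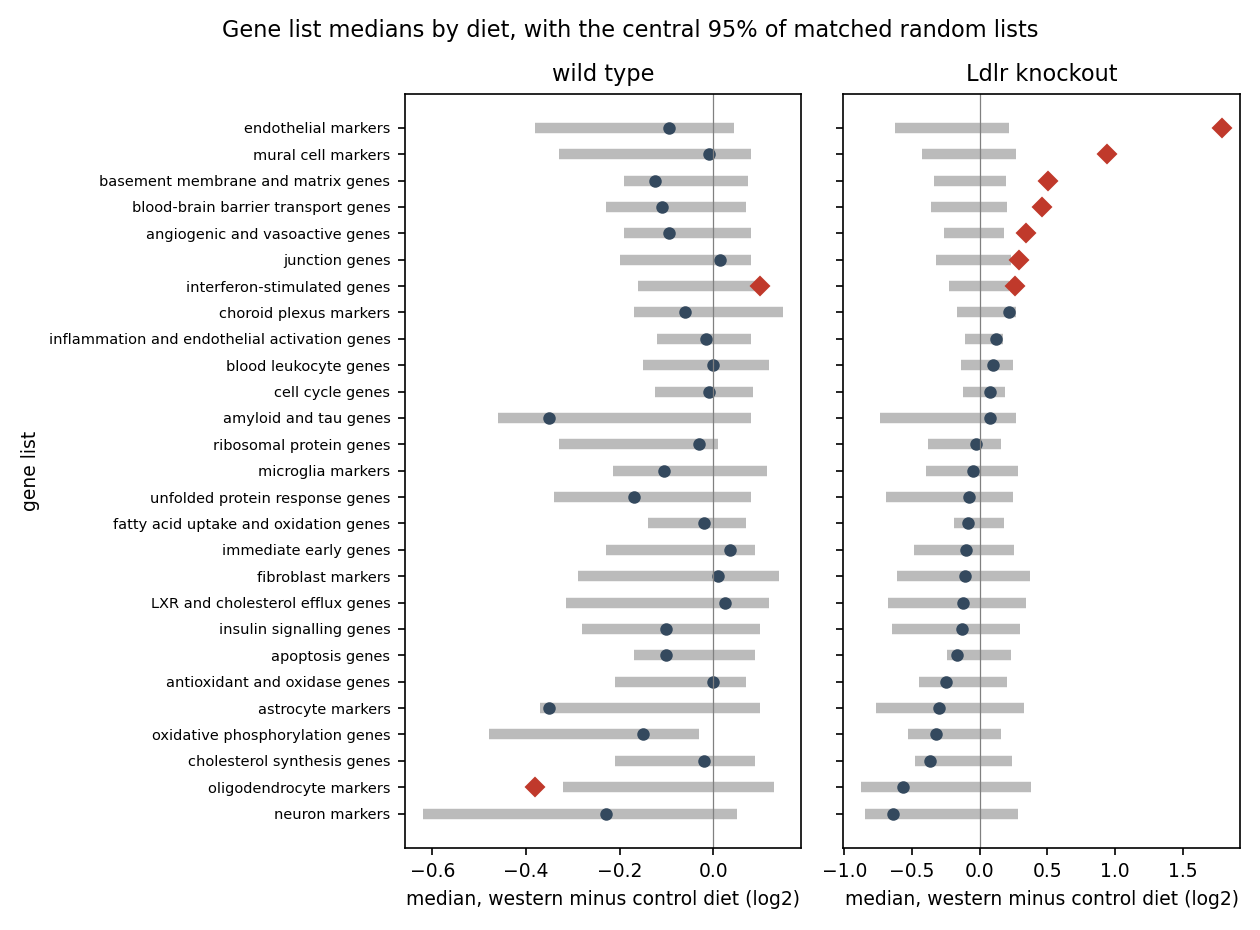
Median difference of western minus control diet in log2 signal of 27 gene lists fixed beforehand, in wild type on the left and Ldlr knockout on the right, over grey bars for the central 95% of 10000 matched random lists. Red diamonds mark the 2 lists in wild type and the 7 lists in knockout whose medians lie outside those bars; the axes of the panels differ.

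Set side by side, 21 genes were higher on western diet in both genotypes, 227 were lower in both and 101 went in opposite directions. Rap1b, a GTPase of cell adhesion (at least 2.68 in wild type, 2.01 in knockout), was among the shared genes. Cryab, a small heat shock protein of glia and muscle (-2.65 and -3.12), Ndufc2 of respiratory complex I (-2.66 and -2.03), the neurofilament gene Ina (-2.15 and -3.66), Vps26a of the retromer (-2.32 and -2.25), Slk (-2.23 and -2.32), Srp72 of the signal recognition particle (-2.25 and -2.19), Nckap1 (-2.03 and -2.34), Sytl2 (-2.02 and -2.74) and Rab26os (-3.52 and -3.80) were lower in both. Drawing the calls of each genotype at random among genes of like brightness gives 15.0 genes higher in both, 189 lower in both and 117 opposite. The correlation of both diet differences across genes, which are not independent replicates, was 0.0481. Under quantile normalization 180 genes went the same way and 199 opposite ways.

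The difference between the diet differences, knockout minus wild type, describes whether the diet acted alike in both genotypes. It was 1 or more for 1390 genes and -1 or less for 1861. Ndufa11 (6.33), Gstm7 (5.65) and Abcb1a (5.52) were among the highest, and Fbxl16 (-6.70) among the lowest. Pecam1 (4.13) among endothelial markers and Rgs5 (4.16) among mural markers were higher, and 17 of 23 endothelial and 9 of 12 mural markers had a value of 1 or more. In wild type 17 and 15 of 24 endothelial and 8 and 9 of 17 mural markers lay above the floor, control diet first. A diet difference could show less there, so these values largely follow the knockout diet difference. Slc2a1, at -1.42 in wild type and 1.87 in knockout, had a value of 3.29. Of the 3251 genes past 1 in size, 1624 had an array at or below the floor. Nid1, Purg, Zfp955b, Eng and Pdgfrb were among these, and no value is given for them here. Klf6, an injury-responsive transcription factor, was lower in wild type (-1.99) and higher in knockout (2.25).

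The comparison of knockout with wild-type mice on control diet asks what loss of the receptor did without the diet. Nearly all genes past 2-fold were higher on the knockout array, 8498 against 34 lower, and the median difference of all genes was 0.89, so differences below are also set against genes of like brightness. Vsnl1, a neuronal calcium sensor (6.05), Selenot, a selenoprotein of the endoplasmic reticulum (6.06), Syt17 (at least 5.75), Dcn, the fibroblast proteoglycan decorin (at least 5.23), Aph1a (5.66) and the ADP/ATP translocase Slc25a5 (5.62) were among the 10 highest. Among neuron markers Calb1 was higher by 5.28 and Camk2a by 5.15, and the list median of 2.14 lay inside the range of random lists (percentile 26.3). The 34 lower genes included Slc7a5 (-2.21), Ankle2 (-1.87) and Rab24 (-1.78), and, with the knockout array below the floor, Rbmxl1 (-2.46 or lower), Rhno1 (-1.72 or lower), Zfp772 (-1.28 or lower) and the oligodendrocyte gene Opalin (-1.11 or lower). Each of these was brightest on the wild-type control-diet array, and none was lower in knockout on western diet. Their values here therefore rest on that single wild-type array.

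Of the 27 lists, endothelial markers alone lay outside the central 95% on control diet. Their median difference of 1.19 was lower than that of random lists of like brightness (1.92, percentile 0.03), a call kept in 3 of 4 alternatives and lost under quantile normalization (percentile 8.09). The matching on all 4 arrays includes their bright signal in knockout mice on western diet and overstates that gap: matched on the arrays compared alone, random lists had a median of 1.56 (percentile 1.92). Slco1a4 (3.59) and Tek (3.52) were high among them. Mural cell markers had a median of 1.39 against 1.51 (percentile 33.9), with Acta2, smooth muscle actin (4.79), and Tagln (3.93) the highest. Bace1 (at least 4.79), Fabp5 (5.43) and Acadm (4.78) were among the highest of their lists. Each was also lower on western diet than on control diet in knockout, and Aph1a and Syt17 were among the 10 lowest there. The knockout control-diet array enters both differences, so a high value on it gives both, and the fall is no separate observation. The percentiles of the 26 lists inside ran from 5.48 to 95.8. Quantile normalization gave 1152 higher and 850 lower genes and loess 1032 and 924, while centring the arrays on their medians gave 4015 and 147, so the near absence of lower genes depended on the scaling. The wild-type array was at or below the floor for 6 of the 10 highest genes and the knockout array for 5 of the 10 lowest. Among all genes past 2-fold in this comparison, 3982 (46.7%) had an array at or below the floor.

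On western diet endothelial, mural and basement membrane lists lay above random lists of like brightness, and transport genes (median 1.25 against 1.32, percentile 35.8), junction genes (percentile 82.7) and angiogenic genes (percentile 96.0) lay inside the central 95%. The knockout array here is also that of the diet comparison in knockout. Its bright vessel genes enter both comparisons, so this one is no separate check. Matched on the arrays compared alone, endothelial markers stayed at percentile 100, while mural cell markers (95.9) and basement membrane genes (91.4) lay inside. Mgp (7.08), Rnf125 (at least 6.61), Zbtb14 (at least 6.68), Ywhaq, a 14-3-3 protein (6.65), Nid1 (at least 6.45), Chmp5 of the ESCRT machinery (6.48) and Rgs5 (6.47) were among the 10 highest, with 8416 genes higher, 22 lower and a median of all genes of 0.94. Endothelial markers had a median of 3.94 against 1.77 in random lists (percentile 100), with all 23 above the limit higher, among them Slco1a4 (6.15), Cldn5 (5.49), Pecam1 (5.40) and Slco1c1, a thyroid hormone transporter (5.16). Mural cell markers had a median of 2.41 against 1.40 (percentile 99.55), with Acta2 (6.16), Pdgfrb (5.82) and Vtn (5.67). Basement membrane and matrix genes had a median of 1.58 against 1.23 (percentile 98.6), with Lamb2 at 4.43.

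The transport genes Slc6a6 (at least 5.50) and Slc22a8 (5.37), the interleukin 6 receptor Il6ra (5.17) and Klf6 (6.23) were high on western diet as well, within lists whose medians lay inside the central 95%, as did 24 of the 27, with percentiles from 9.13 to 96.0. Among the 22 lower genes were Nrgn, a calmodulin-binding protein of dendrites (-2.15), Purg (-1.96), Fbxl16 (-1.42), Rab3c of synaptic vesicles (-1.39) and the glutamate receptor gene Gria3 (-1.36). Of 18 neuron markers 14 were higher and 1, Nrgn, was lower. Quantile normalization gave 1369 higher and 1230 lower genes, loess 1030 and 1023, and centring the arrays 3043 and 146. The dimmer array was at or below the floor for 3 of the 10 highest and 3 of the 10 lowest genes. An array lay at or below the floor for 4475 (53.0%) of all genes past 2-fold. The wild-type and knockout arrays differed in overall signal, so genotype and any difference between the arrays in handling could not be separated.

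**Figure D4:**
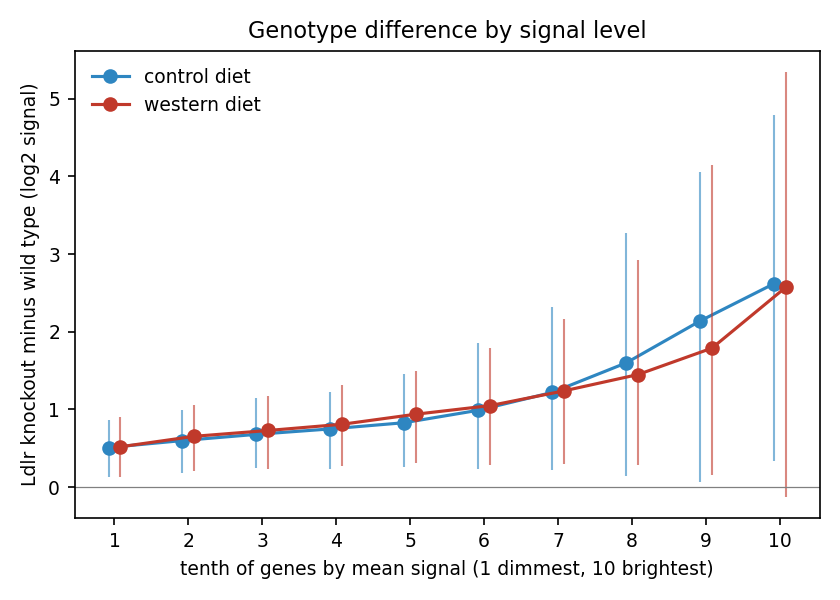
Knockout minus wild-type difference in log2 signal in 10 equal bins of genes ranked by mean signal, on control diet (blue) and western diet (red). Points are medians and lines span the central 95% of genes; the medians run from 0.51 to 2.62 on control diet and from 0.52 to 2.58 on western diet.

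On both diets 6872 genes were higher in knockout, 1 was lower and 24 went opposite ways, with 6636, 0.0839 and 47.5 from random draws at like brightness, and a correlation of 0.375 across genes. Quantile normalization gave 333 higher and 262 lower on both diets against 240 and 124 from such draws, with 167 opposite against 333, and loess gave 149 and 284 against 157 and 148, with 257 opposite against 304. Vsnl1 (6.05 on control diet, 5.43 on western diet), Tspan31 (at least 5.39 and 5.89), Lgals1, galectin-1 (5.27 and 6.28), Acot13, a thioesterase (5.22 and 4.99), Ei24 (at least 4.68 and 4.85), Arrb1, an arrestin (4.87 and 5.05), and Acta2 (4.79 and 6.16) were among the 10 largest shared differences. The gene lower on both diets, chosen after its values were seen, was the microRNA locus Mir290a (-2.16 on control diet, -1.59 or lower on western diet).

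Knockout mice on western diet against wild-type mice on control diet combine both factors. Each of these arrays also enters comparisons above, so the values here are no separate check of those. Zbtb14 (at least 6.66), Rnf125 (at least 6.59), Nid1 (at least 6.43), Tom1 (at least 6.68), Mgp (6.77), Sez6l2 (6.76) and Lgals1 (6.34) were among the 10 highest and Ppp1r7 (-2.75), Rab26os (-2.63), Rbmxl1 (-2.34 or lower), Me1, malic enzyme (-1.94 or lower), and Hadh (-1.85) among the 10 lowest. Of 11100 genes 7828 were higher and 74 lower, with a median of all genes of 0.91. Endothelial markers had a median of 3.32 against 1.55 in random lists (percentile 100), with Ptprb at 6.09, Cldn5 at 5.76, Pecam1 at 5.52 and Eng at 5.32 or more. Mural cell markers had a median of 2.39 against 1.25 (percentile 99.9), with Pdgfrb (at least 6.07) and Acta2 (6.15), and basement membrane genes lay at percentile 98.6, with Lamb2 (3.75).

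Angiogenic genes, with a median of 1.43 (percentile 99.2), and junction genes, with 1.45 (percentile 97.51), were each called in 1 of 4 alternatives. Matched on the arrays compared alone they lay inside the central 95% (94.6 and 94.5), as did basement membrane genes (93.3), while endothelial (100) and mural cell markers (99.46) stayed outside. The neuron marker Camk2a was higher by 5.62, and the neuron median of 1.73 lay inside the range of random lists (percentile 34.2), as did the medians of 22 of the 27 lists. Quantile normalization gave 1324 higher and 1142 lower genes, loess 1124 and 1188, and centring the arrays 2698 and 338. The dimmer array was at or below the floor for 6 of the 10 highest and 5 of the 10 lowest genes. An array lay at or below the floor for 4037 (51.1%) of all genes past 2-fold.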

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

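The tests of the bright knockout arrays and of the vascular genes were chosen after the results were seen, and those of the wild-type diet differences were written before theirs.

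Of 27 gene lists 20 lay inside the central 95% of matched random lists for the difference between both diet differences. Of the others, 4 had medians above 0 in knockout and below 0 in wild type and passed a stricter limit chosen after the data were seen. Their wild-type medians (-0.095, -0.01, -0.11 and -0.125, in the order below) lay inside the central 95% of matched lists and show no opposite response. Members of each list lay at or below the wild-type floor, which limits what could be seen there. Endothelial markers had a median difference between the diet differences of 1.74 (percentile 100), mural cell markers of 1.37 (percentile 100), blood-brain barrier transport genes of 0.55 (percentile 99.92) and basement membrane and matrix genes of 0.515 (percentile 99.9). Angiogenic genes (0.38) and inflammation genes (0.25, percentile 98.3) had the same signs and did not pass that limit. Without the members that are endothelial or mural markers, transport genes had a value of 0.25 (percentile 92.8), inside the central 95%. These differences between genotypes were not tested, as each group is 1 array. A signal also appeared in data that the comparisons leave out: 912 probe sets without a gene symbol lay above the floor on all 4 arrays.

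Endothelial and mural markers were higher on western diet in knockout mice, 26 of 35 (74.3%) by 1 or more, and 1 was lower. A higher signal of the whole western-diet array is argued against by its 95th percentile of signal, 5.71 against 5.94 on control diet, while the endothelial median was higher by 1.79. The 75th percentile was lower too (3.16 against 3.26), and the 99th was nearly equal (8.16 against 8.14). The medians over all probe sets, 2.53 on the western-diet array against 2.48, lie below the floors and cannot decide. That array also held 890 fewer genes above the floor, but each array has its own floor (2.66 and 2.78, control diet first), so this count alone cannot decide. Chance detection of single transcripts is argued against by the endothelial median, which lay at percentile 100 of matched random lists. A larger share of vessel against surrounding tissue in the western-diet capture may account for the pattern, but the share of markers restates it, and the neuron median (-0.64 against -0.21 in matched lists, percentile 8.67) lay inside the central 95%, or just below it (2.49) with lists matched on the arrays compared alone. Synaptic vesicle genes (-0.93, percentile 1.81) and glutamate and GABA receptor genes (-0.94, percentile 1.29) lay below it and go with that explanation, but those lists were chosen after the data were seen, with members noticed among the largest differences. Astrocyte (percentile 32.1), oligodendrocyte (12.4) and microglia markers (46.0), also of surrounding tissue, lay inside the central 95%. Proteasome genes, a list of no cell type chosen after as well, lay lower still (-1.21, percentile 0.115). A larger vessel share and a response of vessel cells to the diet, which was not tested, cannot be told apart with 1 pool of mice per group.

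The knockout arrays were brighter than the wild-type arrays on both diets. A single constant added to every log2 value is argued against by bins of genes ranked by mean signal. Between the dimmest and brightest of 10 bins the median genotype difference ran over a span of at least 2.055 on either diet. A constant factor on the signal stays open, since background would shrink the differences of dim genes. Background would not shrink those of the brightest genes. The 13 genes with a mean signal of 10 or more had medians of 0.94 on control diet and 0.81 on western diet. Those of the brightest bin were 2.62 and 2.58. These genes are few and cannot decide for the rest. The ranking also includes the knockout arrays, so the span cannot decide on such a factor. A lower yield of cDNA or lower RNA quality in the wild-type arrays may also account for the brighter knockout arrays. Ribosomal protein genes were lower in wild type by at least 1.40 more than chemosensory receptor genes. That value restates the pattern, as other genes of like brightness were lower too (percentiles 74.2 and 88.7). A constant factor, lower yield and an effect of the genotype, which was not tested, cannot be told apart, since each genotype has its own arrays.

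The diet differences past 2-fold in wild-type mice were mostly lower values on western diet as deposited, but not under quantile normalization, with 821 higher and 746 lower. Loss of dim transcripts to the floor could account for few of them, as 15.8% had an array at or below the floor. Where such genes had other probe sets above the floor, 60.9% of those differed in the same direction, less than a change of the whole transcript would give. Most differences past 2-fold were lower, so unrelated probe sets need not split evenly in direction. The share that chance would give was not computed. These other probe sets belong to 42 genes and are not independent. By 1 or more, 29 differed the same way and 18 the opposite way. Across 344 other probe sets of all genes above the expression limit the correlation was 0.0894. A change of the transcript and a difference in single probe sets cannot be told apart for these genes, which have few other probe sets. A response to the diet stays open and untested, and so does uneven amplification of transcripts well above the floor.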

How the results depend on the processing

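The alternatives of genes above the floor, of centred arrays and of lists matched on the arrays compared alone were chosen after the data were seen, and the others were planned before. Where a value moved by over 1.5 times the cause was not tested, except that the lower threshold admits more genes and the stricter filters keep fewer genes by construction.

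Under quantile normalization 821 genes were higher with diet in wild type and 935 lower with diet in knockout. Knockout against wild type gave 1152 higher and 850 lower genes on control diet and 1369 and 1230 on western diet, and the combined comparison gave 1324 and 1142. With diet 199 genes went opposite ways in the genotypes, and with genotype 595 went the same way and 167 opposite ways on both diets. Under cyclic loess 260 genes were higher and 374 lower with diet in wild type, 1032 and 924 with genotype on control diet, 1030 and 1023 on western diet, and 1124 and 1188 in the combined comparison. With diet 133 genes went the same way in both genotypes, and with genotype 433 went the same way and 257 opposite ways.

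With the expression limit at the 75th percentile, 5004 genes were higher in knockout on control diet, 4694 on western diet and 4322 in the combined comparison, and 4311 went the same way on both diets. At a 1.5-fold threshold 424 genes were higher and 1389 lower with diet in wild type, and 1755 and 3220 in knockout. The lower genes were 56 with genotype on control diet, 48 on western diet and 150 in the combined comparison, and the difference between diet differences passed for 2509 genes upward and 2982 downward. With diet 638 genes then went the same way and 429 opposite ways, and with genotype 62 opposite ways.

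Among genes above the floor on the arrays compared, 4533 were higher and 17 lower with genotype on control diet, 3953 and 13 on western diet, and 3824 and 42 in the combined comparison. The difference between diet differences passed for 718 genes upward and 909 downward, and with genotype 2846 genes went the same way and 12 opposite ways. With the arrays centred on their medians, 4015 genes were higher and 147 lower with genotype on control diet, 3043 and 146 on western diet and 2698 and 338 in the combined comparison, with 1854 the same way and 70 opposite ways.

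No named gene's difference reversed under quantile normalization, loess or the mean of a gene's probe sets. Of 120 differences among the highest and lowest genes, 120 stayed past 1 under quantile normalization, 120 under loess and 116 with the mean of probe sets, and of 308 differences of list members and other named genes 237, 256 and 292 did. The sizes were less stable: of the 120, 64, 60 and 22 moved in the same order, and of the 308, 56, 41 and 8. The 120 were chosen as the largest on the deposited values, so their staying past 1 is a weak check. The knockout western-diet array enters the diet comparison in knockout, the western-diet genotype comparison and the combined one, so their list calls are not separate findings. Of the list calls, 6 of 7 with diet in knockout, 0 of 2 in wild type, 0 of 1 with genotype on control diet, 3 of 3 on western diet and 3 of 5 in the combined comparison held under all 4 alternatives fixed beforehand that bear on them. With random lists matched on the arrays compared alone 7 of 7, 1 of 2, 1 of 1, 1 of 3 and 2 of 5 held in the same order, and neuron markers with diet in knockout (percentile 2.49) became called. Lists not called became called in 6 cases under quantile normalization, 5 under loess, 10 with members above the limit alone and 1 with the mean of probe sets. Among them with members above the limit were microglia markers (percentile 99.9), interferon-stimulated genes (99.8), inflammation genes (99.8) and leukocyte genes (99.4) with genotype on western diet. With all measured members these lists lay at percentiles 84.4, 93.2, 90.4 and 54.8 in the same order. The leukocyte value rests on 3 of 11 measured members. Of those 11, 1 lay above the floor in wild type on western diet. The limit uses the mean of all arrays, so it can admit members bright in knockout alone. Signal over background limits the wild-type arrays most, where 6478 and 6041 genes lay above the floor, and 3987 genes did so on all 4 arrays. Leaving out arrays in turn was not possible with 1 array per group. No paired analysis was possible because each group is 1 array of pooled RNA.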

Other observations

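The 6 gene lists, the RNA classes and the Ldlr neighbour values relative to the median of all genes were chosen after the data were seen, several list members having first been noticed among the genes with the largest differences, so these lists are not independent evidence; the other neighbour values were planned.

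On western diet in knockout mice, transcription factors of endothelial cells were higher and synaptic and proteasome genes lower. Of 15 endothelial transcription factors above the expression limit 7 were higher and 0 lower, among them Tbx3 (2.65), Lef1, which acts in Wnt signalling at the blood-brain barrier (2.52), Fli1 (2.37) and Epas1 (1.84), with a list median of 0.78 (percentile 100). Of 26 synaptic vesicle genes 13 were lower, including Syt5 (-4.03) and Pclo (-3.03), and Rab3a was the 1 higher (1.11), with a median of -0.93 (percentile 1.81). Of 18 glutamate and GABA receptor genes 9 were lower, including Gabrb2 (-4.02) and Gria3 (-2.83), with a median of -0.94 (percentile 1.29). Of 26 proteasome genes 14 were lower, including Psmb4 (-2.97) and Psmc5 (-2.72), and Psma1 was the 1 higher (2.16), with a median of -1.21 (percentile 0.115). Neuropeptide genes had a median of -0.23 (percentile 15.7), with 5 of 13 lower, namely Vip (-2.94 or lower), Cck (-2.26), Scg2 (-1.96), Sst (-1.80) and Tac1 (-1.72). Mitochondrially encoded genes had a median of -0.26, and most of them are brighter than nearly all genes of the brightest bin, so no percentile is given for them. With diet in wild type the percentiles were 50.5 for endothelial transcription factors, 97.2 for synaptic vesicle genes, 29.9 for receptor genes, 92.3 for proteasome genes and 93.1 for neuropeptide genes, all inside the central 95%, though synaptic vesicle genes lay outside (98.1) with random lists matched on the arrays compared alone. Mitochondrially encoded genes had a median genotype difference of 1.02 on control diet and 0.995 on western diet. All 13 genes with a mean signal of 10 or more had medians of 0.94 and 0.81. Members of the list are among those genes, so the list is in part compared with itself and nothing is concluded from the nearness. With genotype on control diet the percentiles of the other lists were 46.2 for endothelial transcription factors, 99.6 for synaptic vesicle genes, 40.9 for receptor genes, 95.04 for proteasome genes and 23.8 for neuropeptide genes. On western diet they were 100, 13.2, 26.2, 0.86 and 28.0 in the same order.

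Among long non-coding RNAs 3 of 429 were higher and 17 lower with diet in wild type, and 22 higher and 46 lower in knockout. Rian, an imprinted transcript, was lower in both (-1.49 in wild type, -2.99 in knockout). In wild type the higher ones were Pantr1 (1.36), Zfas1 (1.24) and BC064078 (at least 1.13). In knockout Snhg14 was lower (-4.15) and Dubr higher (2.66). Of 37 small nucleolar RNA loci 13 were lower and 1 higher with diet in wild type, and 11 lower and 5 higher in knockout. The higher ones, named after their values were seen, were Snora62 (2.59) in wild type and Snord66 (4.15), Snora7a (at least 3.47), Snord71 (1.42), Snord17 (1.24) and Snord13 (1.17) in knockout. Of 135 microRNA loci 15 were lower and 3 higher in wild type, the latter, named after as well, Mir1954 (1.71), Mir694 (at least 0.75) and Mir28c (at least 1.11), and 24 were lower and 14 higher in knockout, among them Mir679 (at least 5.71). Values of such loci are those of the probe set and need not be those of the mature RNA.

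Probe sets annotated to several haemoglobin genes stood at 3.33 and 4.25 in wild type and 7.48 and 9.12 in knockout, control diet first, on the brightest of them, and at 2.23, 2.01, 5.71 and 8.19 on the next. Of 5 such probe sets 0 were higher with diet in wild type and 3 in knockout. Among 3459 probe sets with no symbol or several that passed the expression limit, 43 were higher and 261 lower with diet in wild type and 299 and 442 in knockout. Of other probe sets of genes past 2-fold, 62.3% differed in the same direction with diet in knockout.

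Alleles of the strain in which the knockout allele was made may have been carried along beside it and may differ in expression from those of C57BL/6J. The median size of the genotype difference among the 100 genes around Ldlr lay at percentile 83.15 of matched random sets on control diet and 64.56 on western diet. Relative to the median of all genes it lay at percentile 11.28 and 95.35. The first pair argued against an effect on the whole stretch, but the shift of the knockout arrays enters it, and the recentred pair went different ways on the diets, so an effect of flanking alleles and none cannot be told apart here.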
